A study of Mus musculus with 12 samples.

How the data were processed

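RNA was sequenced from a light membrane fraction of mouse brain in which myelin was enriched. Male wild type c57Bl6/N mice, an inbred laboratory strain, were used at postnatal day 18 (P18), postnatal day 75 (P75), 6 months and 24 months, with 3 samples per age and 12 in all. The labels number the samples of each age and do not say whether each came from a separate animal. The sources used here do not give the RNA extraction, the library construction, the strand setting of the read counting or any sequencing batch, so no value within a batch can be given.

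The deposited table holds 1 signal value per gene and sample, a gene read count that the authors divided by 1 size factor per sample and rounded to 2 decimals. The submitters' processing notes name TopHat for alignment, HTSeq for counting, DESeq for normalization and the mouse build mm9, without versions. The unit was checked on the values: in each of the 12 columns 100% of the values were whole multiples of a single step, within a tolerance of 0.0061, so the step gave the size factor and the whole reads could be recovered. In 3 columns the step lay within 1% of 1 and was read from the whole column. All 12 columns were used. The table lists 21937 genes by symbol and gives no coordinates, so no positions are given. Reads shared between paralogs or with pseudogene copies may have been split or dropped in the counting, which leaves the levels of ribosomal protein genes, Fth1, Ftl1, Eef1a1, Hnrnpa1, Hspe1, Lyz1, Lyz2, Mt1, Mt2, C4b, Amy1, Ly6c1, the H2 genes, the haemoglobin genes, the Pcdhg cluster and Zbed6 uncertain.

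Depth ranged from 20299052 to 27214385 recovered reads per sample. Shares of single samples carry 95% Wilson confidence intervals, and a gene at 0 reads is given a floor of 3 reads. Intervals and floors cover counting error only, because amplified reads are not independent molecules. A gene was tested when its value reached 10 in at least 3 of the 12 samples, which left 14987 genes. Values were analysed as log2(value + 1), so fold changes of genes with low values are understated.

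The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, fitted to all 12 samples in 4 age groups so that the groups shared an estimate of the spread. Consecutive ages were compared (P75 against P18, 6 months against P75, 24 months against 6 months), and a moderated F test over the 3 contrasts asked whether a gene differed at any age. All tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. P-values measure the spread between these samples. Genes at consecutive contrasts share the samples of the middle age, so the 3 comparisons are not independent.

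The comparisons, the tests, the filter, the gene lists and the rule for naming genes were set before the data were examined. There were 30 lists: structural myelin proteins, mature oligodendrocytes, newly formed oligodendrocytes, oligodendrocyte precursors, cholesterol synthesis, fatty acid and sphingolipid synthesis, astrocytes, microglia, activated microglia, neurons, neuronal development, endothelium, mural cells and fibroblasts, choroid plexus and ependyma, erythrocytes, lymphocytes, MHC class I, MHC class II, interferon response, complement and acute phase, cell cycle, extracellular matrix of immature white matter, immediate early genes, heat shock and chaperones, iron handling, Mbp mRNA transport and splicing, nuclear-retained RNA, cytosolic ribosomal proteins, the nuclear-encoded respiratory chain and mitochondrially encoded genes. None of the symbols of the mitochondrially encoded list was found in the table, and those genes were not analysed here. Each list with at least 5 tested members was tested with camera from limma at a preset correlation of 0.01, which compares its genes with all others, and p-values were adjusted over 27 lists and 3 contrasts (81 tests). The same test with a correlation estimated per list was run beside it. The erythrocyte list had 4 tested members and the lymphocyte list 3, too few for the set test.

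The genes named were, per comparison, the 8 with the largest rise and the 8 with the largest fall among genes that passed, had a mean value of at least 50 and did not overlap between the ages (10% of genes would be free of overlap by chance with 3 samples against 3). Unnamed transcripts, clone symbols, pseudogenes and small RNAs were left out of these. To them were added up to 4 members of each list with the lowest adjusted p, a fixed set of structural myelin genes that included Mbp, Mobp, Cnp, Mag and Mog, and the 10 genes with the highest mean value. Genes outside this rule are said to have been chosen after their values were seen.

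The share of a list in a sample is the sum of its values over the sum of all values. It was compared across ages with an exact permutation test of the one-way F statistic over all 15400 partitions of 12 samples into 4 groups of 3, adjusted over 29 lists. The smallest p it can give is 6.49e-05. For 3 samples against 3 no exact test can go below p = 0.1, so pairs of ages are given as values. These shares were computed with Python 3.11.15 and NumPy 2.4.6, and plots were drawn with matplotlib 3.10.9.

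The limma test was tested on simulated data made from the recovered reads, with 200 genes changed in each comparison. At a fold of 2 it found 92.5% of the changed genes for P75 against P18, 86.6% for 6 months against P75 and 83.6% for 24 months against 6 months. At a fold of 1.5 it found 55.2%, 58.2% and 70.1% in the same order. It made 6, 5 and 7 false calls among 14932, 14932 and 14927 genes. The simulated genes varied independently, with exact size factors, no length trend and only 200 genes changed. False calls from correlated genes, from normalization or from differences between preparations are therefore not measured. In simulated shares without a difference the permutation test gave p under 0.05 in 5.25% of 400 draws.

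Alternatives were pseudocounts of 5 and 0.1, no filter, a filter at 50, TMM factors, median-of-ratios factors, quantile normalization, rescaling outside the 20 most abundant genes, fits of only the 6 samples compared, a robust variance fit, the replicate number as a block, a minimum absolute log2 fold change of 1, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, other denominators of the shares, and leaving out each of the 12 samples in turn. The trends of each library with transcript length and with GC content, the deviation of Mbp from its age mean as a covariate and the comparison of 24 months with P75 were added after seeing the data. Lengths and GC contents came from the longest transcript of each gene in a mouse GENCODE annotation and were found for 13506 of the 14987 tested genes (90.1%). The trend of each library was fitted to all of these genes, members of the lists included. Its removal also recentred each library. The deposited values are on another build, but only lengths and base composition were taken from the annotation.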

Results

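Myelin, the membrane that oligodendrocytes wrap around axons, was isolated from mouse brain as a light membrane fraction, and the RNA in it was sequenced at 4 ages. P18 falls in the period of active myelination, P75 in young adulthood, and 6 and 24 months in adulthood and old age. Each age had 3 samples, and each sample held 20299052 to 27214385 reads in genes and 16949 to 17261 detected genes. Of the 14987 genes tested, 11597 (77.4%) differed at some age (limma F test). The highest mean lay at P18 for 3907 of them, at P75 for 2058, at 6 months for 2622 and at 24 months for 3010. The samples of each age lay together on the first principal component, which held 57.9% of the variance: -57.5 to -54.7 at P18, -22.7 to -15.5 at P75, 33.3 to 44.6 at 6 months and 33.1 to 43.1 at 24 months. The second component held 17.3% and did not follow the order of the ages. On it P18 (16 to 19.8) and 6 months (17.2 to 29.2) lay apart from P75 (-37.9 to -21.2) and 24 months (-18.97 to -6.90). P18 replicate 3 stood apart on the third (5.80% of the variance), at -24.3 against 3.59 and -0.61 in the other P18 samples.

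Mbp, which encodes myelin basic protein and whose mRNA is carried along oligodendrocyte processes to the sheath, was the most abundant transcript. It took 15.1 ± 5.65% of all normalised counts at P18, 5.61 ± 1.23% at P75, 6.32 ± 1.87% at 6 months and 6.4 ± 1.09% at 24 months (SD, n = 3). Single P18 samples ranged from 9.47% (95% Wilson interval 9.46 to 9.48) in replicate 3 to 20.8% (20.8 to 20.8) in replicate 2. Fth1, the heavy chain of the iron store ferritin, ranked next by its mean over the ages and took 0.682 ± 0.239%, 2.13 ± 0.231%, 2.35 ± 0.593% and 3.72 ± 1.0% at the successive ages. Plekhb1, a membrane-binding protein of oligodendrocytes, took 0.219 ± 0.093%, 0.593 ± 0.102%, 0.674 ± 0.178% and 0.742 ± 0.104%. Mobp, Snap25, Bcas1, Eef1a1, Kif5a and Trp53inp2 were also among the 10 most abundant transcripts by that mean. The 20 structural myelin genes together took 17.4 ± 6.07% at P18, 6.94 ± 1.35% at P75, 7.92 ± 2.03% at 6 months and 7.9 ± 1.13% at 24 months (exact permutation test over 4 ages, adjusted p = 0.0208).

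The shares of 19 of the 29 lists differed between ages in the exact permutation test. Iron handling genes, most of whose share is Fth1, took 0.774 ± 0.253% at P18, 2.24 ± 0.231% at P75, 2.48 ± 0.587% at 6 months and 3.85 ± 0.991% at 24 months (adjusted p = 0.00132). Mature oligodendrocyte genes took 0.541 ± 0.147% at P18, 1.35 ± 0.106% at P75, 1.49 ± 0.21% at 6 months and 1.6 ± 0.0656% at 24 months (adjusted p = 0.00686). Microglial genes took 0.0441 ± 0.00251% at P18, 0.069 ± 0.00425% at P75, 0.0806 ± 0.00686% at 6 months and 0.126 ± 0.0172% at 24 months, at the smallest p the test can give (adjusted p = 0.000471). The neuron list took 1.22 ± 0.235% at P18, 1.42 ± 0.0996% at P75, 1.53 ± 0.105% at 6 months and 1.44 ± 0.0828% at 24 months and did not pass (adjusted p = 0.134). Astrocyte genes took 0.765 ± 0.0302% at P18, 0.889 ± 0.0105% at P75, 0.92 ± 0.0545% at 6 months and 0.865 ± 0.052% at 24 months.

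**Figure D1:**
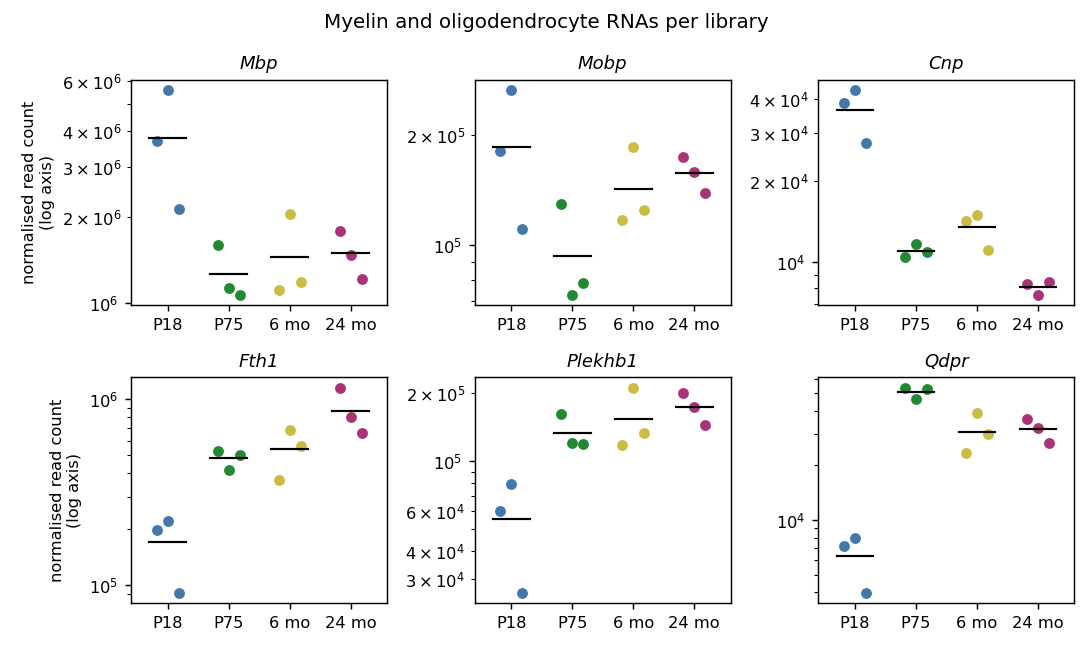
Normalised read counts (log axis) of 6 oligodendrocyte transcripts in each of the 12 libraries, by age, with 3 points per age and a bar at their mean. Cnp means fell from 36481 at P18 to 10986 at P75 while Qdpr means rose from 6378 to 51111, and Mbp spread from 2134340 to 5580860 at P18 alone.

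The comparison of P75 with P18 asked how the RNA of the myelin-enriched fraction differed between active myelination and the young adult. Qdpr, which recycles the cofactor tetrahydrobiopterin and is abundant in mature oligodendrocytes, rose by 3.06 ± 0.22 on the log2 scale (SE, n = 3 at each age here and in the values that follow), from 6378 ± 2105 to 51111 ± 3889 normalised counts (SD). Cnp, a phosphodiesterase of non-compact myelin, fell by 1.71 ± 0.15, from 36481 ± 7996 to 10986 ± 597. Sirt2, a deacetylase found in the sheath, fell by 2.66 ± 0.12. Neat1, a long non-coding RNA of the nucleus, rose by 2.56 ± 0.16. In all, 6051 of 14987 genes (40.4%) changed, 3247 up and 2804 down, and 691 of them by at least 1 on the log2 scale. Higher genes made up 53.7% of those changed, but 46.1% with the length trend and 46.5% with the GC trend removed and 49.6% after quantile normalization. Removing a trend also recentred each library and kept only the 13506 genes with a length. This balance therefore depends on the centring, and its shift cannot be credited to the trends.

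Of the 20 structural myelin genes 3 rose, 11 fell and 6 did not pass (3 up and 13 down adjusted over the list alone), with a median log2 fold change of -0.53. Cldn11, the claudin of the radial component, fell by 1.29 ± 0.13, and Mal, a raft protein of compact myelin, fell by 1.13 ± 0.15. The surface glycoprotein gene Mog fell by 1.11 ± 0.13 and the adhesion molecule gene Mag fell by 0.64 ± 0.12. The camera test called the list lower (adjusted p = 0.00116), with adjusted p = 0.585 with an estimated correlation. Mbp had a log2 fold change of -1.5 ± 0.60 and did not pass (adjusted p = 0.0561). It passed in edgeR (-1.6, adjusted p = 0.0013), without P18 replicate 3 (-1.87, adjusted p = 0.0176), without 6 months replicate 1 (-1.5, adjusted p = 0.0483) or with the length trend removed (-1.55, adjusted p = 0.0401), with adjusted p from 0.0013 to 0.158 over the alternatives. Mobp, a small basic protein gene whose mRNA also lies in the sheath, fell by 0.95 ± 0.31 (adjusted p = 0.0209). Mobp did not pass without P18 replicate 1 (-0.92, adjusted p = 0.0542), without P18 replicate 2 (-0.64, adjusted p = 0.107), without P75 replicate 2 (-0.79, adjusted p = 0.0925) or without P75 replicate 3 (-0.84, adjusted p = 0.0783), with adjusted p from 1.56e-05 to 0.107 over the alternatives.

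Of 24 genes of mature oligodendrocytes 15 rose, 1 fell and 8 did not pass (15 up and 1 down adjusted over the list alone). Among them the alarmin gene Il33 rose by 2.08 ± 0.13 and Ptgds, which makes a prostaglandin, rose by 1.82 ± 0.12, whereas Gsn, an actin-severing protein, fell by 1.55 ± 0.14. Camera called the list higher (adjusted p = 2.20e-05), with adjusted p = 0.546 with an estimated correlation. Of 19 genes of newly formed oligodendrocytes 2 rose, 17 fell and 0 did not pass (2 up and 17 down adjusted over the list alone), with a median of -0.94. By summed counts the list went the other way, from 0.41 ± 0.0741% at P18 to 0.502 ± 0.090% at P75 (exact permutation test over 4 ages, adjusted p = 0.0511), and most of the share at P75 is Bcas1, a protein of premyelinating oligodendrocytes, which rose by 1.07 ± 0.32. Bcas1 did not pass without P18 replicate 3 (0.62, adjusted p = 0.0519) or without P75 replicate 1 (0.87, adjusted p = 0.0646), with adjusted p from 2.17e-06 to 0.0646 over the alternatives. Gpr17, a receptor of committed precursors, fell by 2.29 ± 0.22, and the small GTPase gene Rras2 fell by 1.62 ± 0.12. The kinase gene Fyn fell by 1.0 ± 0.077 and Rassf10 fell by 2.28 ± 0.24. Camera called this list lower (adjusted p = 1.09e-10), with adjusted p = 0.116 with an estimated correlation. Of 19 precursor genes 3 rose, 10 fell and 6 did not pass (3 up and 10 down adjusted over the list alone), with camera adjusted p = 0.00248 and adjusted p = 0.51 with an estimated correlation. The lineage transcription factor genes Olig2 and Olig1 had log2 fold changes of -1.31 ± 0.11 and -1.12 ± 0.091.

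Lipid synthesis genes were lower at P75 in part. Of 22 cholesterol synthesis genes 2 rose, 12 fell and 8 did not pass (3 up and 12 down adjusted over the list alone), with camera adjusted p = 0.000295 and adjusted p = 0.51 with an estimated correlation. Mvd, an enzyme of the mevalonate pathway, fell by 1.15 ± 0.12. Of 21 fatty acid and sphingolipid genes 6 rose, 9 fell and 6 did not pass (6 up and 9 down adjusted over the list alone), and the list was not called (adjusted p = 0.467). In it Gal3st1, which makes the myelin lipid sulfatide, fell by 1.5 ± 0.17, while Srebf1, a regulator of fatty acid synthesis, rose by 1.26 ± 0.086. Of 20 neuronal development genes 1 rose, 12 fell and 7 did not pass (1 up and 12 down adjusted over the list alone), with camera adjusted p = 1.43e-05 and adjusted p = 0.412 with an estimated correlation. Marcksl1, which binds actin, fell by 2.38 ± 0.081, from 11962 ± 412 to 2301 ± 64.3, and Gap43, a growth cone protein gene, fell by 0.63 ± 0.083.

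Of 76 genes of cytosolic ribosomal proteins 57 rose, 0 fell and 19 did not pass (62 up and 0 down adjusted over the list alone), with a median of 0.65. Rps3a rose by 1.36 ± 0.19 and Rps6 rose by 1.23 ± 0.18. Camera gave adjusted p = 3.50e-11, and adjusted p = 0.595 with an estimated correlation. Of 21 microglial genes 14 rose, 0 fell and 7 did not pass (15 up and 0 down adjusted over the list alone), among them the protease gene Ctss, which rose by 1.03 ± 0.12 (camera adjusted p = 0.000467, adjusted p = 0.546 with an estimated correlation). Of 12 MHC class I genes 9 rose, 0 fell and 3 did not pass (10 up and 0 down adjusted over the list alone), with H2-K1 as an example (0.87 ± 0.093). Their camera adjusted p = 0.000134, and adjusted p = 0.473 with an estimated correlation. Of 16 complement and acute phase genes 9 rose, 1 fell and 6 did not pass (10 up and 1 down adjusted over the list alone), with adjusted p = 0.0108 and adjusted p = 0.51 with an estimated correlation, while their summed share went from 0.0653 ± 0.0131% to 0.0578 ± 0.00162%. Spp1, which encodes the secreted protein osteopontin and stands in the activated microglia list, rose by 1.48 ± 0.087, and in that list 7 rose, 0 fell and 13 did not pass of 20 (7 up and 0 down adjusted over the list alone, camera adjusted p = 0.0301, adjusted p = 0.51 with an estimated correlation). The activated microglia call was lost without P18 replicate 2 (adjusted p = 0.053) or without P75 replicate 3 (0.0519), with adjusted p from 0.0125 to 0.053 over all alternatives at the preset correlation.

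The largest changes also included genes of other cells. S100a5 and Omp, both markers of olfactory neurons, rose by 4.65 ± 0.58 and 2.65 ± 0.52. At P18 they were uneven between samples, with S100a5 at 129.5, 14.7 and 10.04 and Omp at 177.1, 50.9 and 16.1 counts in replicates 1, 2 and 3. Alas2, the first enzyme of haem synthesis in red cells, fell by 3.3 ± 0.21. In the erythrocyte list 3 of 4 tested genes fell and 1 did not pass (0 up and 4 down adjusted over the list alone). The haemoglobin genes Hba-a1, Hba-a2, Hbb-b1 and Hbb-b2 were listed at 0 in every library. Reads shared between these paralogs may have been dropped in the counting, so the zeros do not show that red cell RNA was absent. Il23a, a cytokine subunit gene, fell by 3.93 ± 0.31, and Srd5a1, a steroid reductase gene, fell by 3.01 ± 0.18. Parvb, an adaptor of integrin signalling, fell by 2.43 ± 0.14. Abca8a, a membrane transporter gene, rose by 3.01 ± 0.20, and the protease inhibitor gene Serpinb1a rose by 2.84 ± 0.28. The matrix protein genes Dmp1 and Efemp1 had log2 fold changes of 2.58 ± 0.15 and 2.41 ± 0.19.

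Camera called 4 more lists at P75. Mural cells and fibroblasts were called higher, and the other 3 lower. Mural cells and fibroblasts had 7 up and 3 down of 17, or 9 and 4 adjusted over the list alone (adjusted p = 0.0437, adjusted p = 0.546 with an estimated correlation). Cell cycle genes had 2 up and 10 down of 30, or 2 and 10 adjusted over the list alone (adjusted p = 0.0276, adjusted p = 0.435 with an estimated correlation). Immediate early genes had 0 up and 8 down of 17, or 0 and 8 adjusted over the list alone (adjusted p = 0.00424, adjusted p = 0.595 with an estimated correlation). Mbp mRNA transport and splicing had 1 up and 6 down of 15, or 1 and 6 adjusted over the list alone (adjusted p = 0.0487, adjusted p = 0.51 with an estimated correlation). The mural cells and fibroblasts call was lost with the stricter filter (adjusted p = 0.0607), without P18 replicate 3 (0.0801), without P75 replicate 1 (0.077), without 6 months replicate 1 (0.0512), without 6 months replicate 2 (0.0511) or with Mbp as a covariate (0.0547), with adjusted p from 0.0151 to 0.0801 over all alternatives at the preset correlation. The cell cycle call was lost with the stricter filter (adjusted p = 0.388), without P18 replicate 1 (0.0628) or with the length trend removed (0.0539), with adjusted p from 0.0163 to 0.388 over all alternatives at the preset correlation. The immediate early genes call was lost without P18 replicate 3 (adjusted p = 0.0969), with adjusted p from 5.35e-05 to 0.0969 over all alternatives at the preset correlation. The Mbp mRNA transport and splicing call was lost with the stricter filter (adjusted p = 0.0705), without P18 replicate 1 (0.05005), without P18 replicate 3 (0.0635), without P75 replicate 3 (0.067), without 6 months replicate 1 (0.053), without 6 months replicate 2 (0.0511), without 24 months replicate 1 (0.0501) or without 24 months replicate 2 (0.0502), with adjusted p from 0.0331 to 0.0705 over all alternatives at the preset correlation.

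Several lists were not called at P75. Astrocyte genes had 7 up and 2 down of 18, or 7 and 2 adjusted over the list alone (adjusted p = 0.145). Neuronal genes had 5 up and 8 down of 24, or 5 and 8 adjusted over the list alone (adjusted p = 0.584). Endothelial genes had 3 up and 1 down of 16, or 3 and 0 adjusted over the list alone (adjusted p = 0.758). Choroid plexus and ependyma had 6 up and 1 down of 13, or 6 and 2 adjusted over the list alone (adjusted p = 0.106). MHC class II had 5 up and 0 down of 7, or 5 and 1 adjusted over the list alone (adjusted p = 0.0727). The MHC class II list was called without P18 replicate 2 (adjusted p = 0.0379) or with the GC trend removed (0.045), with adjusted p from 0.0379 to 0.134 over these alternatives. Interferon response had 7 up and 2 down of 25, or 7 and 2 adjusted over the list alone (adjusted p = 0.846). Extracellular matrix of immature white matter had 3 up and 6 down of 18, or 3 and 6 adjusted over the list alone (adjusted p = 0.624). Heat shock and chaperones had 2 up and 2 down of 16, or 2 and 1 adjusted over the list alone (adjusted p = 0.824). Iron handling had 3 up and 2 down of 13, or 3 and 3 adjusted over the list alone (adjusted p = 0.811). Nuclear-retained RNA had 2 up and 2 down of 7, or 2 and 2 adjusted over the list alone (adjusted p = 0.869). Respiratory chain genes had 1 up and 10 down of 73, or 0 and 6 adjusted over the list alone (adjusted p = 0.132). The respiratory chain (nuclear) list was called without P75 replicate 3 (adjusted p = 0.0162) or with the length trend removed (0.0133), with adjusted p from 0.0133 to 0.845 over these alternatives. In the lymphocyte list 1 of 3 tested genes rose and 1 fell (1 up and 1 down adjusted over the list alone). The camera test pointed down for neurons, with a median of 0.028 and a mean of -0.015. It pointed down for heat shock (-0.077 and 0.021), extracellular matrix (0.0090 and -0.11) and nuclear-retained RNA (-0.21 and 0.18). It pointed up for endothelium (-0.025 and 0.074) and interferon response (0.076 and -0.086).

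At P75 15 of 27 lists were called, 7 higher and 8 lower, and with an estimated correlation 0 passed, or 3 at an unadjusted p. Other splits of the same 6 samples called 8 to 13 lists and 0 genes by limma. Each of them mixes the 2 ages, which puts part of the age difference into the spread within groups and leaves part between them. Neither count therefore gives a chance level. List calls at the preset correlation carry little weight, because 0 passed with an estimated one. Genes passing in the direction of each list's median were counted again with the trends removed. With the length trend removed their number moved by over 1.5 times for the respiratory chain (10 to 21 of 73 lower). It also did so for nuclear-retained RNA (2 to 4 of 7 lower). With the GC trend removed it moved by over 1.5 times only for endothelium (1 to 0 of 16 lower).

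The comparison of 6 months with P75 asked how the RNA of the myelin-enriched fraction differed between the adult and the young adult. Gabbr2, a subunit of the GABA-B receptor, rose by 3.46 ± 0.18, from 108 ± 24.2 to 1195 ± 284 normalised counts. Syt1, the calcium sensor of transmitter release, rose by 2.34 ± 0.13, from 3851 ± 345 to 19472 ± 2226. Kif5a, a neuronal kinesin, rose by 1.51 ± 0.21. Genes of ribosomal proteins and of the respiratory chain were lower, such as Rpl35 (-1.21 ± 0.17) and the complex I gene Ndufa6 (-1.32 ± 0.12). In all, 7859 genes (52.4%) changed, 4054 up and 3805 down, and 1422 of them by at least 1 on the log2 scale. Higher genes made up 51.6% of those changed, but 45.8% with the length trend and 48.2% with the GC trend removed and 48.2% after quantile normalization. Here too the balance depends on the centring of each library.

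Of 76 ribosomal protein genes 1 rose, 72 fell and 3 did not pass (1 up and 73 down adjusted over the list alone), with a median of -0.86 (camera adjusted p = 8.22e-16, adjusted p = 0.546 with an estimated correlation). Their share went from 7.28 ± 0.782% to 4.13 ± 0.792% of all counts. Of 73 nuclear-encoded respiratory chain genes 2 rose, 59 fell and 12 did not pass (3 up and 60 down adjusted over the list alone), with a median of -0.77 (camera adjusted p = 1.08e-15, adjusted p = 0.51 with an estimated correlation). The complex I gene Ndufa5 fell by 1.28 ± 0.13, Uqcrb of complex III fell by 1.06 ± 0.10, Rps25 fell by 1.12 ± 0.16 and Rpl27 fell by 1.08 ± 0.13. Short transcripts were lower at 6 months in general: the median log2 fold change was -0.33 in the shortest 20% of genes and 0.15 in the longest. With the length trend of each library removed, the medians were -0.37 for ribosomal proteins and -0.29 for the respiratory chain. Then 41 of 75 and 41 of 73 genes passed as lower. Rpl35 was then at -0.68 and Ndufa6 at -0.91, and both passed, as did Ndufa5 at -0.70, Rpl27 at -0.40 and Uqcrb at -0.29.

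**Figure D2:**
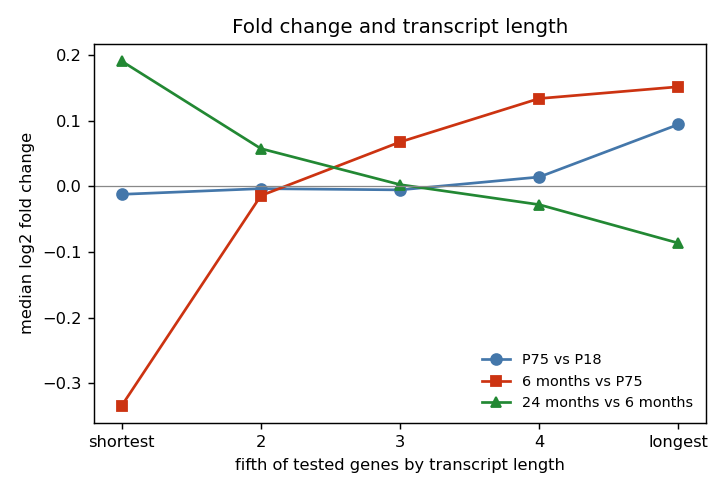
Median log2 fold change in each 20% of genes ordered by length of the longest annotated transcript, for the 3 comparisons, with 2701 or 2702 genes per point. The shortest 20% lay at -0.33 for 6 months against P75 and at 0.19 for 24 months against 6 months, and the longest at 0.15 and -0.09.

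Of 24 neuronal genes 14 rose, 4 fell and 6 did not pass (15 up and 4 down adjusted over the list alone), with camera adjusted p = 0.00829 and adjusted p = 0.623 with an estimated correlation. The vesicular glutamate transporter gene Slc17a7 rose by 1.41 ± 0.16 and the NMDA receptor gene Grin1 rose by 1.2 ± 0.14. Snap25, a protein of synaptic vesicle fusion, fell by 0.68 ± 0.17. The summed neuron share overlapped between these ages, at 1.36 to 1.53% at P75 and 1.43 to 1.64% at 6 months. From which part of the fraction these transcripts came was not tested. The largest rises included genes outside the neuron list. Pdyn, the precursor of dynorphin, rose by 4.34 ± 0.49. Ano3, of the anoctamin family, rose by 3.05 ± 0.28, and Pnmal2 rose by 3.38 ± 0.21. The protocadherin genes Pcdhgc5 and Pcdhgc3 had log2 fold changes of 3.7 ± 0.43 and 3.02 ± 0.17, and Zbed6, which lies within another gene, rose by 3.38 ± 0.46.

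Of 20 structural myelin genes 5 rose, 0 fell and 15 did not pass (5 up and 0 down adjusted over the list alone), and the list was not called (adjusted p = 0.189). Mag rose by 0.51 ± 0.12 and Gpr37, a receptor of mature oligodendrocytes, rose by 0.80 ± 0.17. Mbp (0.16 ± 0.60), Mobp (0.62 ± 0.31), Cnp (0.28 ± 0.15) and Mog (0.22 ± 0.13) did not pass, with adjusted p from 0.0969 to 0.837. Mobp passed without P18 replicate 3 (0.62, adjusted p = 0.0381), without P75 replicate 1 (0.88, adjusted p = 0.0328) or with Mbp as a covariate (0.62, adjusted p = 0.000406), with adjusted p from 0.000406 to 0.312 over the alternatives. Cnp passed without P18 replicate 3 (0.28, adjusted p = 0.0365), without 6 months replicate 3 (0.41, adjusted p = 0.0396) or with Mbp as a covariate (0.28, adjusted p = 0.0466), with adjusted p from 0.0365 to 0.347 over the alternatives. Mog passed without P18 replicate 3 (0.22, adjusted p = 0.0277) or with the length trend removed (0.37, adjusted p = 0.0288), with adjusted p from 0.0277 to 0.385 over the alternatives. Of 21 fatty acid and sphingolipid genes 12 rose, 0 fell and 9 did not pass (12 up and 0 down adjusted over the list alone, camera adjusted p = 0.00405, adjusted p = 0.546 with an estimated correlation). With the length trend removed 6 of 20 rose, and the median of 0.33 became 0.18. Fads2, a desaturase of polyunsaturated fatty acids, rose by 1.97 ± 0.15. Of 22 cholesterol genes 11 rose, 2 fell and 9 did not pass (11 up and 2 down adjusted over the list alone), short of a call (adjusted p = 0.062). The cholesterol synthesis list was called without P18 replicate 3 (adjusted p = 0.0462), without P75 replicate 2 (0.048), without P75 replicate 3 (0.0488) or without 6 months replicate 3 (0.0464), with adjusted p from 0.0462 to 0.137 over these alternatives. Srebf2, the transcription factor that drives cholesterol synthesis, rose by 1.75 ± 0.11.

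Of 19 precursor genes 13 rose, 3 fell and 3 did not pass (13 up and 3 down adjusted over the list alone, adjusted p = 0.0757). With the length trend removed 7 of 19 rose. The oligodendrocyte precursor list was called without 6 months replicate 3 (adjusted p = 0.0463), with adjusted p from 0.0463 to 0.169 over these alternatives. The matrix gene Tnr rose by 1.97 ± 0.18 whereas Olig1 fell by 0.95 ± 0.091. Of 19 genes of newly formed oligodendrocytes 4 rose, 7 fell and 8 did not pass (4 up and 7 down adjusted over the list alone, adjusted p = 0.384), and of 24 of mature oligodendrocytes 5 rose, 3 fell and 16 did not pass (3 up and 2 down adjusted over the list alone, adjusted p = 0.814). Of 30 cell cycle genes 2 rose, 13 fell and 15 did not pass (2 up and 13 down adjusted over the list alone), with camera adjusted p = 0.0375 and adjusted p = 0.435 with an estimated correlation. Cenpa, the histone variant of centromeres, fell by 1.78 ± 0.21. The cell cycle call was lost with the stricter filter (adjusted p = 0.229) or without 6 months replicate 2 (0.0608), with adjusted p from 0.0212 to 0.229 over all alternatives at the preset correlation. The list of mural cells and fibroblasts was called higher. Mural cells and fibroblasts had 5 up and 0 down of 17, or 5 and 0 adjusted over the list alone (adjusted p = 0.0458, adjusted p = 0.546 with an estimated correlation). The mural cells and fibroblasts call was lost without P75 replicate 2 (adjusted p = 0.0747), without 6 months replicate 1 (0.0565), without 6 months replicate 2 (0.0513), with the GC trend removed (0.0565) or with Mbp as a covariate (0.051), with adjusted p from 0.0244 to 0.0747 over all alternatives at the preset correlation.

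The metallothionein genes Mt2 and Mt1, whose proteins bind zinc and copper, had the log2 fold changes -2.41 ± 0.19 and -2.08 ± 0.18. Wdfy1, an adaptor of innate immune signalling, fell by 2.46 ± 0.093, and Hif3a, a subunit of the hypoxia-inducible factors, fell by 2.35 ± 0.23. Efcab7 fell by 2.03 ± 0.19 and the amylase gene Amy1 fell by 1.91 ± 0.20. Hoxa5, a homeobox gene of the hindbrain and spinal cord, fell by 1.97 ± 0.61. It did not pass without 6 months replicate 1 (-1.69, adjusted p = 0.0622), with adjusted p from 1.75e-06 to 0.0622 over the alternatives. S100a5 fell by 2.02 ± 0.58, and did not pass with the length trend removed (-1.21, adjusted p = 0.0974), with adjusted p from 8.05e-07 to 0.0974 over the alternatives. Lyz2, the lysozyme gene of macrophages and microglia, rose by 1.31 ± 0.17.

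The remaining lists were not called at 6 months. Microglial genes had 8 up and 2 down of 21, or 8 and 2 adjusted over the list alone (adjusted p = 0.0757). The microglia list was called without P75 replicate 3 (adjusted p = 0.0487), without 6 months replicate 3 (0.0447) or with the length trend removed (0.00149), with adjusted p from 0.00149 to 0.148 over these alternatives. Activated microglia had 8 up and 1 down of 20, or 8 and 1 adjusted over the list alone (adjusted p = 0.0594). The activated microglia list was called with the stricter filter (adjusted p = 0.0492), without P75 replicate 3 (0.0297) or with the length trend removed (0.00406), with adjusted p from 0.00406 to 0.108 over these alternatives. MHC class I had 5 up and 0 down of 12, or 4 and 0 adjusted over the list alone (adjusted p = 0.291). MHC class II had 4 up and 0 down of 7, or 5 and 0 adjusted over the list alone (adjusted p = 0.0534). The MHC class II list was called with a pseudocount of 5 (adjusted p = 0.0466), without P18 replicate 2 (0.044), without P18 replicate 3 (0.0459), without 6 months replicate 2 (0.0415), without 24 months replicate 2 (0.0477) or with the length trend removed (0.0126), with adjusted p from 0.0126 to 0.0816 over these alternatives. Interferon response had 7 up and 2 down of 25, or 7 and 2 adjusted over the list alone (adjusted p = 0.254). Complement and acute phase had 6 up and 1 down of 16, or 6 and 1 adjusted over the list alone (adjusted p = 0.117). The complement and acute phase list was called with the length trend removed (adjusted p = 0.0281), with adjusted p from 0.0281 to 0.251 over these alternatives. Astrocyte genes had 6 up and 3 down of 18, or 6 and 3 adjusted over the list alone (adjusted p = 0.573). Neuronal development had 5 up and 10 down of 20, or 5 and 11 adjusted over the list alone (adjusted p = 0.211). Endothelial genes had 4 up and 4 down of 16, or 4 and 4 adjusted over the list alone (adjusted p = 0.706). Choroid plexus and ependyma had 8 up and 1 down of 13, or 8 and 1 adjusted over the list alone (adjusted p = 0.0563). The choroid plexus and ependyma list was called with the stricter filter (adjusted p = 0.0492) or with the length trend removed (0.0129), with adjusted p from 0.0129 to 0.0841 over these alternatives. Extracellular matrix of immature white matter had 8 up and 1 down of 18, or 8 and 1 adjusted over the list alone (adjusted p = 0.0954). Immediate early genes had 7 up and 2 down of 17, or 8 and 2 adjusted over the list alone (adjusted p = 0.157). Heat shock and chaperones had 5 up and 2 down of 16, or 4 and 2 adjusted over the list alone (adjusted p = 0.594). Iron handling had 5 up and 2 down of 13, or 5 and 3 adjusted over the list alone (adjusted p = 0.432). Mbp mRNA transport and splicing had 6 up and 4 down of 15, or 6 and 4 adjusted over the list alone (adjusted p = 0.691). Nuclear-retained RNA had 0 up and 3 down of 7, or 0 and 3 adjusted over the list alone (adjusted p = 0.691). For nuclear-retained RNA camera pointed down, with a median of 0.11 and a mean of -0.13. In the erythrocyte list 1 of 4 genes fell and in the lymphocyte list 1 of 3 fell (1 down in each adjusted over the list alone).

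At 6 months 6 of 27 lists were called against P75, 3 higher and 3 lower, and with an estimated correlation 0 passed, or 2 at an unadjusted p. Other splits of the same 6 samples, which mix the 2 ages and so give no chance level, called 4 to 18 lists and 0 genes. Genes passing in the direction of each list's median were again counted with the trends removed. With the length trend removed their number moved by over 1.5 times in other lists too. Higher genes went from 5 to 2 of 16 for heat shock and chaperones and from 6 to 3 of 15 for Mbp mRNA transport and splicing. Removing the GC trend moved the number by over 1.5 times in none of the lists.

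The comparison of 24 months with 6 months asked how the RNA of the myelin-enriched fraction differed between old age and the adult. Immune transcripts were higher at 24 months. Clec7a, a pattern recognition receptor of activated microglia, rose by 2.98 ± 0.29, from 19.4 ± 8.58 to 152 ± 22.5 normalised counts. Cst7, a cysteine protease inhibitor of the same cells, rose by 3.41 ± 0.39, from 7.86 ± 2.36 to 91.2 ± 1.42. The complement gene C4b rose by 2.05 ± 0.17, from 461 ± 72.9 to 1893 ± 129. B2m, the light chain of MHC class I, rose by 0.88 ± 0.085, from 3549 ± 127 to 6562 ± 672. Cnp fell by 0.72 ± 0.15, from 13432 ± 2049 to 8101 ± 467. In all, 2876 genes (19.2%) changed, 1626 up and 1250 down, and 245 of them by at least 1 on the log2 scale. The count fell to 1279 without 6 months replicate 1, 1499 without 6 months replicate 2, 1527 without 24 months replicate 1 and 1244 without 24 months replicate 2. Higher genes made up 56.5% of those changed, but 43.0% with the length trend and 38.0% with the GC trend removed and 48.2% after quantile normalization. Here too the balance depends on the centring of each library.

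Of 20 activated microglia genes 17 rose, 0 fell and 3 did not pass (18 up and 0 down adjusted over the list alone), with a median log2 fold change of 1.34 (camera adjusted p = 2.07e-14, adjusted p = 0.0881 with an estimated correlation). Lyz2 rose by 1.79 ± 0.17 and Cd68, a lysosomal protein gene of phagocytes, rose by 1.18 ± 0.14. Lgals3, a galectin of phagocytes, rose by 2.07 ± 0.27 and Cd52, a surface glycoprotein of leukocytes, rose by 1.75 ± 0.21. The related lysozyme gene Lyz1 rose by 2.43 ± 0.23. Of 21 general microglial genes 11 rose, 0 fell and 10 did not pass (12 up and 0 down adjusted over the list alone), with a median of 0.64 (camera adjusted p = 1.31e-08, adjusted p = 0.482 with an estimated correlation), or 0.42 with the length trend removed, where 10 of 21 rose. Tyrobp, the signalling adaptor of several myeloid receptors, rose by 1.24 ± 0.12, its partner gene Trem2 rose by 1.03 ± 0.10 and Fcer1g, an antibody receptor chain, rose by 1.03 ± 0.11. By summed counts the general list went from 0.0806 ± 0.00686% to 0.126 ± 0.0172% of all counts and the activated list from 0.321 ± 0.0114% to 0.382 ± 0.052%. Its 3 most abundant members, Apoe, Ctsb and Ctsd, named after their values were seen, held 89.3% of the activated counts at 6 months and had log2 fold changes of 0.16 ± 0.14 (adjusted p = 0.441), 0.27 ± 0.0996 (adjusted p = 0.0632) and 0.48 ± 0.11 (adjusted p = 0.00772). With the length trend removed Tyrobp was at 0.78 and Fcer1g at 0.60. The 24 months samples lay above all 6 months samples for Clec7a (135.7 to 177.7 against 14.2 to 29.3) and Trem2 (686 to 865 against 364 to 397), and Csf1r, whose values at these ages were chosen after they were seen, overlapped (1158 to 1495 against 1198 to 1394).

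Of 16 complement and acute phase genes 11 rose, 0 fell and 5 did not pass (14 up and 0 down adjusted over the list alone, camera adjusted p = 2.67e-10, adjusted p = 0.212 with an estimated correlation). C3 rose by 2.09 ± 0.26, C1qc rose by 0.94 ± 0.10 and C1qa rose by 0.82 ± 0.10. Of 12 MHC class I genes 10 rose, 0 fell and 2 did not pass (11 up and 0 down adjusted over the list alone, camera adjusted p = 1.01e-08, adjusted p = 0.304 with an estimated correlation). H2-K1 rose by 0.89 ± 0.093, H2-D1 rose by 0.62 ± 0.12 and the immunoproteasome gene Psmb8 rose by 1.05 ± 0.16. Of 25 interferon response genes 13 rose, 0 fell and 12 did not pass (19 up and 0 down adjusted over the list alone, camera adjusted p = 4.25e-07, adjusted p = 0.473 with an estimated correlation). Ifi27l2a rose by 1.41 ± 0.27, and Irf9, a transcription factor of interferon signalling, rose by 0.69 ± 0.14. With the length trend removed Ifi27l2a was at 0.90, C1qa at 0.52 and B2m at 0.52. The MHC class II list was also called higher, with its invariant chain gene Cd74 at 0.91 ± 0.20. MHC class II had 3 up and 0 down of 7, or 4 and 0 adjusted over the list alone (adjusted p = 0.0437, adjusted p = 0.51 with an estimated correlation). The MHC class II call was lost without 6 months replicate 2 (adjusted p = 0.0746), without 24 months replicate 2 (0.0761), without 24 months replicate 3 (0.058) or with the length trend removed (0.0582), with adjusted p from 0.0117 to 0.0761 over all alternatives at the preset correlation. In the lymphocyte list 1 of 3 tested genes rose (2 up adjusted over the list alone). Beside the immune lists, the share of choroid plexus and ependyma genes went from 0.135 ± 0.0105% to 0.199 ± 0.0113% without overlap between these ages (0.0595 ± 0.00934% at P18 and 0.117 ± 0.013% at P75, exact permutation test over 4 ages, adjusted p = 0.000807). Most of it is Ttr, the thyroid hormone carrier gene of the choroid plexus, which rose by 0.63 ± 0.12, or by 0.37 with the length trend removed. The 4 tested erythrocyte genes had log2 fold changes of -0.13 to 0.93 and did not pass.

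**Figure D3:**
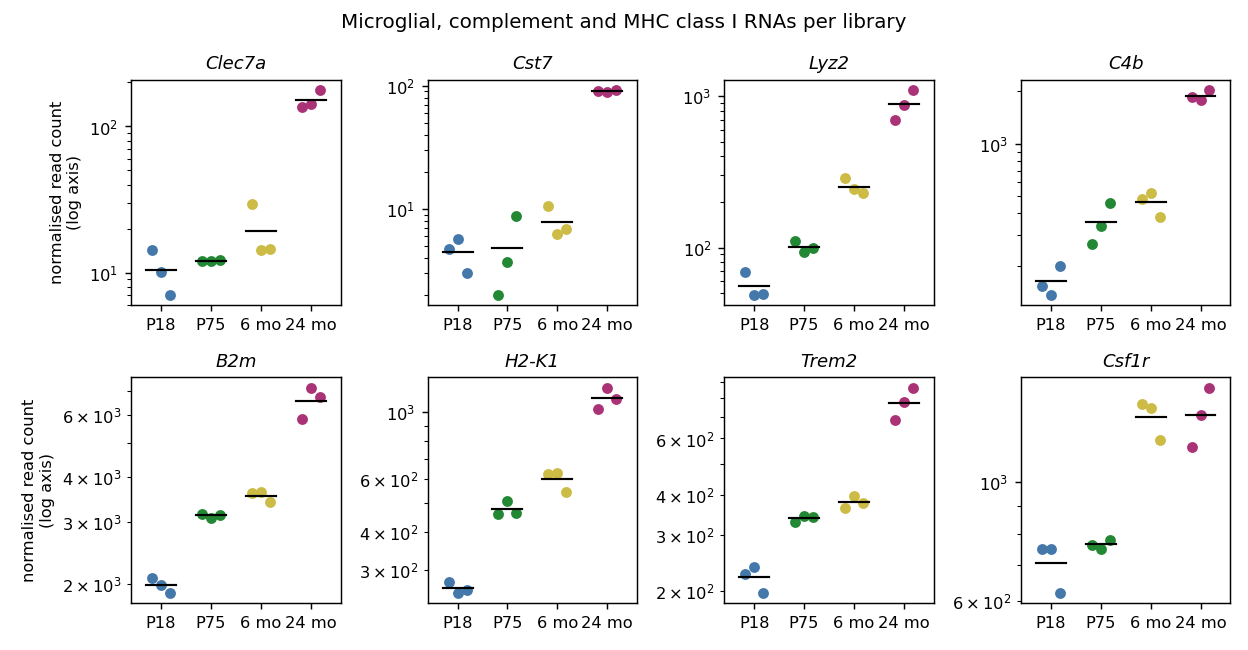
Normalised read counts (log axis) of 8 microglial, complement and MHC class I transcripts in each of the 12 libraries, by age, with 3 points per age and a bar at their mean. Cst7 stayed between 2 and 10.6 up to 6 months and lay between 89.7 and 92.6 at 24 months.

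Of 20 structural myelin genes 1 rose, 3 fell and 16 did not pass (2 up and 3 down adjusted over the list alone), short of a call (adjusted p = 0.0952). The myelin structural proteins list was called without P18 replicate 3 (adjusted p = 0.0322) or without 6 months replicate 3 (0.0325), with adjusted p from 0.0322 to 0.291 over these alternatives. Mbp (0.083 ± 0.60), Mobp (0.17 ± 0.31), Mag (-0.16 ± 0.12) and Mog (-0.28 ± 0.13) did not pass. Mog passed without P18 replicate 3 (-0.28, adjusted p = 0.0196) or with the length trend removed (-0.44, adjusted p = 0.0336), with adjusted p from 0.0196 to 0.351 over the alternatives. Of 19 genes of newly formed oligodendrocytes 0 rose, 7 fell and 12 did not pass (0 up and 9 down adjusted over the list alone, camera adjusted p = 0.00138, adjusted p = 0.466 with an estimated correlation). Gpr17 fell by 1.05 ± 0.22. The summed share of the newly formed oligodendrocyte list went from 0.561 ± 0.0901% to 0.669 ± 0.0847%, with Bcas1 at 0.40 ± 0.32 (adjusted p = 0.389), and Bcas1 passed with Mbp as a covariate (0.40, adjusted p = 0.0166), with adjusted p from 0.0166 to 0.691 over the alternatives. Of 19 precursor genes 0 rose, 3 fell and 16 did not pass (0 up and 3 down adjusted over the list alone, camera adjusted p = 0.0252, adjusted p = 0.546 with an estimated correlation), among them Sox6, a transcription factor of precursors, which fell by 0.74 ± 0.14. The oligodendrocyte precursor call was lost with the stricter filter (adjusted p = 0.0676), without 6 months replicate 1 (0.0556), without 24 months replicate 1 (0.0637) or with the length trend removed (0.0702), with adjusted p from 0.00362 to 0.0702 over all alternatives at the preset correlation. Hapln2, a link protein at nodes of Ranvier, rose by 0.72 ± 0.10, and of 24 mature oligodendrocyte genes 2 rose, 1 fell and 21 did not pass (2 up and 1 down adjusted over the list alone, adjusted p = 0.837). These falls are relative to 6 months. At 24 months against P75 the precursor list had a median of 0.18, with 8 up and 4 down of 19. The newly formed oligodendrocyte list was lower there too, with a median of -0.34 and 2 up and 10 down of 19.

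Of 20 neuronal development genes 0 rose, 7 fell and 13 did not pass (0 up and 7 down adjusted over the list alone, camera adjusted p = 0.00331, adjusted p = 0.51 with an estimated correlation). Dpysl3, a growth cone protein gene, fell by 1.31 ± 0.25, Sox4 fell by 0.87 ± 0.19 and the tubulin gene Tuba1a fell by 0.44 ± 0.089. Of 17 immediate early genes 0 rose, 3 fell and 14 did not pass (0 up and 4 down adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.637 with an estimated correlation). The immediate early genes call was lost without 24 months replicate 1 (adjusted p = 0.0581), with adjusted p from 0.00033 to 0.0581 over all alternatives at the preset correlation. The activity-regulated transcription factor genes Egr3 and Egr2 had log2 fold changes of -2.02 ± 0.40 and -1.15 ± 0.24. Top2a, a topoisomerase of dividing cells, fell by 1.3 ± 0.28, and of 30 cell cycle genes 1 rose, 4 fell and 25 did not pass (1 up and 4 down adjusted over the list alone, adjusted p = 0.10). Irs2, an adaptor of insulin signalling, fell by 1.97 ± 0.33, and the nuclear receptor corepressor gene Nrip1 fell by 1.7 ± 0.23. Pnmal2 fell by 1.74 ± 0.21, Klhl34 fell by 1.49 ± 0.27 and Clvs1 fell by 1.4 ± 0.23. Pcdhgc5 fell by 1.71 ± 0.43, and did not pass without 6 months replicate 1 (-1.54, adjusted p = 0.0674) or without 24 months replicate 1 (-1.34, adjusted p = 0.0712), with adjusted p from 0.0024 to 0.0712 over the alternatives. Plin4, a lipid droplet protein gene, rose by 1.73 ± 0.50, and did not pass without 6 months replicate 1 (1.62, adjusted p = 0.0922), without 6 months replicate 3 (1.52, adjusted p = 0.0748), without 24 months replicate 1 (1.34, adjusted p = 0.119) or without 24 months replicate 2 (1.83, adjusted p = 0.0593), with adjusted p from 0.00292 to 0.119 over the alternatives. At 24 months against P75 the immediate early genes were not lower, with a median of 0.36 and 5 up and 3 down of 17. Neuronal development genes were, with a median of -0.44 and 0 up and 11 down of 20.

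Of 76 ribosomal protein genes 13 rose, 0 fell and 63 did not pass (40 up and 0 down adjusted over the list alone), with a median of 0.41 (camera adjusted p = 9.95e-10, adjusted p = 0.62 with an estimated correlation). Of 73 respiratory chain genes 38 rose, 1 fell and 34 did not pass (45 up and 3 down adjusted over the list alone, camera adjusted p = 5.30e-08, adjusted p = 0.595 with an estimated correlation). Short transcripts were higher at 24 months in general, with a median of 0.19 in the shortest 20% and -0.09 in the longest. With the length trend of each library removed, the median of the ribosomal protein genes was 0.098 and 1 of 75 rose, and that of the respiratory chain, 0.34 before, was -0.0057 and 5 of 73 rose. With the GC trend removed 3 ribosomal protein genes rose. The respiratory chain (nuclear) call was lost with the length trend removed (adjusted p = 0.597), with adjusted p from 5.52e-11 to 0.597 over all alternatives at the preset correlation. Of 7 nuclear-retained RNAs 5 rose, 0 fell and 2 did not pass (6 up and 0 down adjusted over the list alone, camera adjusted p = 0.000134, adjusted p = 0.412 with an estimated correlation). Neat1 rose by 1.31 ± 0.16 and the imprinted transcript Mirg rose by 1.1 ± 0.13. The list for Mbp mRNA transport and splicing was called lower, with the RNA-binding protein gene Hnrnpk at -0.38 ± 0.087. Mbp mRNA transport and splicing had 0 up and 3 down of 15, or 0 and 4 adjusted over the list alone (adjusted p = 0.0498, adjusted p = 0.51 with an estimated correlation). The Mbp mRNA transport and splicing call was lost with the stricter filter (adjusted p = 0.0812), with TMM factors (0.0527), with the replicate number as a block (0.0504), without P18 replicate 1 (0.05005), without P75 replicate 2 (0.0525), without P75 replicate 3 (0.0502), without 6 months replicate 1 (0.0504), without 6 months replicate 2 (0.0996), without 24 months replicate 1 (0.0714), without 24 months replicate 2 (0.0532), with the length trend removed (0.104) or with the GC trend removed (0.0766), with adjusted p from 0.0322 to 0.104 over all alternatives at the preset correlation.

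Other lists were not called at 24 months. Cholesterol synthesis had 3 up and 1 down of 22, or 3 and 1 adjusted over the list alone (adjusted p = 0.883). Fatty acid and sphingolipid synthesis had 1 up and 4 down of 21, or 1 and 4 adjusted over the list alone (adjusted p = 0.291). Astrocyte genes had 2 up and 1 down of 18, or 2 and 1 adjusted over the list alone (adjusted p = 0.419). Neuronal genes had 3 up and 4 down of 24, or 4 and 6 adjusted over the list alone (adjusted p = 0.0954). The neuron list was called with the length trend removed (adjusted p = 0.0398), with adjusted p from 0.0398 to 0.168 over these alternatives. Endothelial genes had 3 up and 0 down of 16, or 3 and 0 adjusted over the list alone (adjusted p = 0.758). Mural cells and fibroblasts had 1 up and 1 down of 17, or 1 and 1 adjusted over the list alone (adjusted p = 0.917). Choroid plexus and ependyma had 1 up and 0 down of 13, or 1 and 0 adjusted over the list alone (adjusted p = 0.394). Extracellular matrix of immature white matter had 3 up and 1 down of 18, or 4 and 1 adjusted over the list alone (adjusted p = 0.956). Heat shock and chaperones had 3 up and 0 down of 16, or 4 and 1 adjusted over the list alone (adjusted p = 0.53). The heat shock and chaperones list was called without 24 months replicate 1 (adjusted p = 0.0312), with adjusted p from 0.0312 to 0.676 over these alternatives. Iron handling had 1 up and 1 down of 13, or 1 and 1 adjusted over the list alone (adjusted p = 0.797). Camera pointed down for 4 lists with a median above 0: cholesterol synthesis (median 0.0024, mean -0.0008), mature oligodendrocytes (0.012, 0.0067), mural cells and fibroblasts (0.012, -0.011) and extracellular matrix (0.056, 0.041). Srebf2 fell by 0.55 ± 0.11, Fads2 fell by 0.82 ± 0.15 and Fasn, the fatty acid synthase gene, fell by 0.44 ± 0.084, while Kdsr, an enzyme of ceramide synthesis, rose by 0.47 ± 0.083. The astrocyte connexin gene Gjb6 rose by 0.47 ± 0.081, and the neuronal enolase gene Eno2 fell by 0.50 ± 0.11 while Snhg11, a long non-coding RNA of neurons, rose by 1.06 ± 0.17. Fth1, already the most abundant transcript after Mbp, had a log2 fold change of 0.70 ± 0.39 and did not pass (adjusted p = 0.219). It passed with Mbp as a covariate (0.70, adjusted p = 0.0159), with adjusted p from 0.0159 to 0.525 over the alternatives. At 24 months against P75 the cholesterol synthesis list had a median of 0.37, with 13 up and 4 down of 22. The fatty acid and sphingolipid list had a median of 0.26 there, with 10 up and 1 down of 21.

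**Figure D4:**
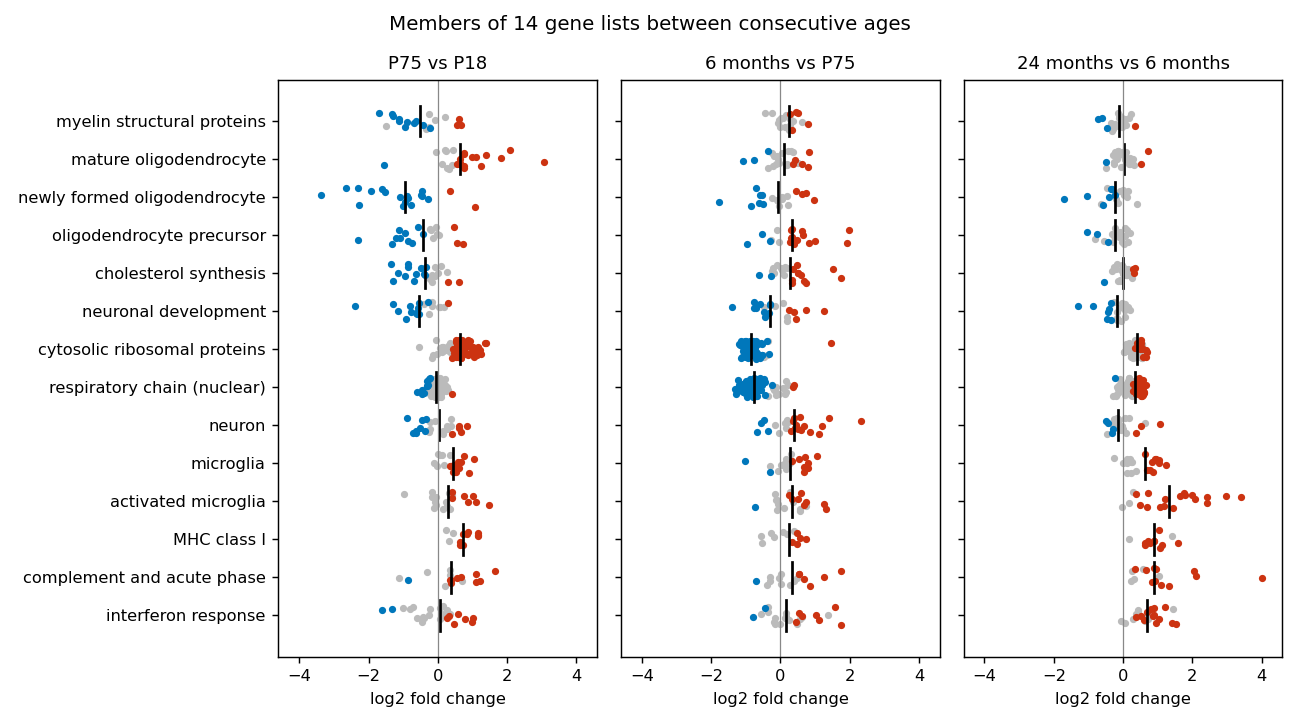
Log2 fold changes of the tested members of 14 gene lists in the 3 comparisons, with coloured points for genes that passed (red higher, blue lower), grey points for the others and a bar at each list's median. The median of activated microglia lay at 1.34 for 24 months against 6 months, and that of ribosomal proteins at 0.65, -0.86 and 0.41 in the 3 comparisons, before any correction for length.

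At 24 months 14 of 27 lists were called against 6 months, 9 higher and 5 lower, and with an estimated correlation 0 passed, or 4 at an unadjusted p. Other splits of the same 6 samples, which mix the 2 ages and so give no chance level, called 7 to 15 lists and 0 genes. Removing the length trend moved the number of genes passing in the direction of the list's median by over 1.5 times in other lists. Higher genes went from 2 to 1 of 24 for mature oligodendrocytes, 3 to 1 of 21 for cholesterol synthesis and 3 to 1 of 16 for endothelium. They went from 1 to 2 of 13 for choroid plexus and ependyma and 3 to 1 of 7 for MHC class II. For heat shock and chaperones they went from 3 to 1 of 16, and for iron handling from 1 to 0 of 13. Lower genes went from 1 to 2 of 17 for astrocytes and 4 to 7 of 30 for cell cycle. Removing the GC trend also moved it by over 1.5 times in other lists. Lower genes went from 3 to 5 of 19 for oligodendrocyte precursors, 1 to 2 of 17 for astrocytes and 4 to 10 of 24 for neurons. They went from 4 to 7 of 30 for cell cycle and 3 to 5 of 15 for Mbp mRNA transport and splicing. Higher genes went from 1 to 0 of 13 for iron handling and 5 to 3 of 7 for nuclear-retained RNA.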

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

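The trends with transcript length and GC content, the Mbp covariate and the comparison with P75 were chosen only after the data were seen. With TMM, median-of-ratios, quantile and rescaled values the counts of changed genes stayed within 1.5 times their main values. With edgeR 5982, 7956 and 3185 genes changed in the 3 comparisons and 11670 at any age, and with DESeq2 5912, 7780, 3278 and 11520. A minimum absolute log2 fold change of 1 left 691, 1422 and 245 genes, by its own construction. Leaving out each sample in turn gave 1244 to 3963 genes for 24 months against 6 months, the highest without P18 replicate 3. Comparing 24 months with P75 in place of 6 months gave 6836 genes, of which 870 were among the 2876 with the same sign. With the replicate number as a block 5871, 7656 and 2583 genes changed, 11377 at any age, and 15, 6 and 13 lists were called. The numbers did not pair the samples: 18 pairs with the same number from different ages correlated at -0.18 to 0.16 after the age means were removed, 3 of them above 0.1, and 6 of 12 samples correlated best with their own number. Lists called went from 15, 6 and 14 to 0, 0 and 0 with an estimated correlation per list, which widens the test where members of a list vary together. With the length trend removed 11 lists were called for 6 months against P75, the cause was not tested, and camera called 0, 0 and 0 when the correlation was estimated as well (2, 1 and 6 at an unadjusted p). No list called in the opposite direction was found under any alternative run on lists. The shares of 17 to 22 lists differed between ages when a sample was left out, against 19 with all. None of the 411 pairs of a named gene and a comparison changed the sign of a call under any alternative run on them. Leaving out 6 months replicate 1 ended 46 of these calls, the most of any sample, and removing the length trend ended 31 among 406 pairs. Depth, 20299052 to 27214385 reads per sample, limits a gene at 0 reads to shares of up to 1.10e-05% to 1.48e-05%.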

Other observations

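The slopes on Mbp of the other structural myelin genes and the comparison of both microglial lists were tests chosen only after the result was seen, as were the criterion and the corrected values for the length trend. Oxt, Avp, Pmch, Hcrt, Hoxb3, Mt3, Cxcl13 and Ccl8 were chosen after their values were seen, as were the P18 values of Hoxa5 and the 24 months values of Mt1, Mt2, Gabbr2, Pcdhgc3, Csf1r, Apoe, Ctsb and Ctsd, and apart from the length trend the alternatives were not run on these. Oxt, the oxytocin precursor, went from 19.3 ± 7.09 normalised counts at P18 to 92.5 ± 16.9 at P75 (2.25 ± 0.24 on the log2 scale, adjusted p = 3.70e-06). Between the same ages Avp (vasopressin) had a log2 fold change of 1.61 ± 0.26 (adjusted p = 0.000147), Pmch (melanin-concentrating hormone) 1.74 ± 0.17 (adjusted p = 2.42e-06) and Hcrt (orexin) 1.62 ± 0.20 (adjusted p = 1.30e-05). Avp rose again from 6 to 24 months (1.01 ± 0.26, adjusted p = 0.0142), but was at 0.54 ± 0.27 with the length trend removed and did not pass (adjusted p = 0.166). Hoxa5 was uneven at P18, with 238.9, 154.8 and 17.1 counts in replicates 1 to 3. Hoxb3 fell by 1.53 ± 0.26 from P75 to 6 months (adjusted p = 0.000164).

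Mt3, the brain metallothionein gene, fell by 1.46 ± 0.14 from P75 to 6 months (adjusted p = 6.53e-07) and rose by 0.53 ± 0.14 to 24 months (adjusted p = 0.015), and Mt1 and Mt2 rose by 0.87 ± 0.18 and 0.98 ± 0.19 in the latter step. Short transcripts as a whole moved the same way in both steps. With the length trend removed Mt3 fell by 0.68 ± 0.092 (adjusted p = 2.22e-05) and was then at 0.047 ± 0.092, which did not pass (adjusted p = 0.765), while Mt1 and Mt2 still rose to 24 months, by 0.58 ± 0.16 (adjusted p = 0.0181) and 0.49 ± 0.15 (adjusted p = 0.0328). Gabbr2 and Pcdhgc3 fell from 6 to 24 months by 1.07 ± 0.18 and 1.17 ± 0.17. Cxcl13, a chemokine that attracts B cells, rose from 4.94 ± 1.38 to 23.5 ± 5.8 counts at 24 months (adjusted p = 0.00891), as did the chemokine gene Ccl8, from 5.53 ± 1.43 to 28.3 ± 15.7 (adjusted p = 0.0188), which did not pass with the length trend removed (1.49 ± 0.55, adjusted p = 0.0694).

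Mbp varied between samples of an age, and 292 of 14986 other genes varied with it (limma slope on the deviation of log2 Mbp from its age mean), 268 with a rising and 24 with a falling slope. Plekhb1 had a slope of 1.04 ± 0.12, Bcas1 1.02 ± 0.11, Trp53inp2 0.97 ± 0.097, Mobp 0.89 ± 0.12, and the motor transport genes Kif1c 0.87 ± 0.084 and Trak2 0.85 ± 0.0995, whereas Mag was at 0.19 ± 0.099. The covariation was not limited to oligodendrocyte genes. The median slope was 0.33 for mature oligodendrocytes (8 of 24 passing upward), 0.32 for ribosomal proteins (5 of 76) and 0.29 for structural myelin genes (3 of 19). For immediate early genes it was -0.43, with 0 of 17 passing. Varying amounts of whole oligodendrocytes would give the other structural myelin genes slopes near 1, but the upper quartile of 19 genes was 0.3834 (median 0.29, median SE 0.11), and it was 0.15 without P18 replicate 3. After rescaling outside the 20 most abundant genes 86.3% of the 292 still passed, and only the real order, 1 of 100 reshuffles of Mbp within ages, reached 292 (highest other 159). The count was 132 without P18 replicate 3, 137 without P18 replicate 2 and 194 without 6 months replicate 2. Every one of the 292 kept its sign in all 12 fits with a sample left out. They were chosen in the fit of the same 12 samples, so their signs could hardly change and this adds no support. A candidate explanation is that the amount of RNA local to the sheath, as against that of cell bodies, varied between preparations, which was not tested.

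Ribosomal protein and respiratory chain genes were lower at 6 months than at P75. Their medians from 6 to 24 months, 0.41 and 0.34, were 0.098 (1 of 75 genes passed as higher) and -0.0057 (5 of 73) with the length trend removed. For the fall, removing the GC trend left the median of the ribosomal protein genes at -0.9074, which argues against that trend. Removing the length trend took it from -0.86 to -0.3693 (41 of 75 genes pass as lower, -0.44 to -0.25 over 12 fits with a sample left out), and missed the bound of -0.43 set beforehand. It argues against the trend as the whole cause only by a criterion chosen after the value was seen, that more than 50% of the members pass, every median with a sample left out lies beyond -0.1 and the list is still called, and that call holds at the preset correlation (adjusted p = 2.09e-06) and not with an estimated one (adjusted p = 0.709 with an estimated correlation). More than 50% of the fall went with the trend. A difference in RNA integrity or size selection between preparations may therefore account for much of it. The trend was fitted to all genes with a length, members of both lists included. A coordinated fall of these genes would thus also shrink when the trend is removed, so age stays open for both parts. For ribosomal protein genes a lasting shift after P75 cannot be told apart from a dip at 6 months. Their median of 24 months against P75, -0.4605, lay between what each would give. Neither shape takes account of P18, and a rise confined to P75 was not tested.

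The immune lists were called higher at 24 months than at 6 months at the preset correlation and none with an estimated one (with an estimated correlation adjusted p = 0.0881 for activated microglia, adjusted p = 0.482 for microglia, adjusted p = 0.212 for complement, adjusted p = 0.304 for MHC class I, adjusted p = 0.51 for MHC class II and adjusted p = 0.473 for interferon response), and a larger share of microglia alone would raise general and activated genes alike. The activated list's median exceeded that of the general list by 0.6944 (1.34 against 0.64, permutation p = 0.00603 over genes, which are not independent, with 0 of 20 activated genes and 3 of 21 general ones in another list), and 10 of 20 activated genes rose by more than the highest general gene, Tyrobp (1.24). By summed counts the order was the other way (0.321 ± 0.0114% to 0.382 ± 0.052% for the activated and 0.0806 ± 0.00686% to 0.126 ± 0.0172% for the general list), so the excess holds for the median member and not for Apoe, Ctsb and Ctsd, which held 89.3% of the activated counts. The 6 months samples do not account for the rise, as the activated median was 1.6767 at 24 months against P75 (19 of 20 genes up), nor does the length trend, without which 18 of 20 genes passed (median 1.23, and 0.42 for the general list). A change of state in microglia or other phagocytes with age, with or without more of them in the fraction, may account for it, and inflow of blood cells or changed recovery of microglial fragments or other tissue with myelin was not tested, although the choroid plexus and ependyma share also went from 0.135 ± 0.0105% to 0.199 ± 0.0113%, with 1 of 13 genes, Ttr, passing.

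Whether a random division of the samples could give such counts can be judged only for all ages together. There 1 of 100 splits, the real one, gave 11597 genes and the highest other gave 2218. That is the smallest share 100 splits can give, so chance is unlikely there but not excluded. For pairs of ages there are 10 splits, too few for a share under 0.05. The real splits gave 6051, 7859 and 2876 genes, and the highest other gave 0 each time. Those other splits mix the 2 ages, which widens the spread within groups, so the 0 does not measure how many genes chance would give. For lists the real splits gave 15, 6 and 14 and the highest others 13, 18 and 15, with as many in 1, 7 and 2 of 10 splits.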
